A study of Homo sapiens with 4 samples.

How the data were processed

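Human cells named B49.5 and J21.c3 were grown in DMEM with 10% serum, per the labels, and 20 µg of DNase-treated total RNA was reverse transcribed with Cy3 or Cy5. On each of the 4 arrays both channels held the same cells. GEO's label fields name the dyes of the channels the other way round from the titles and the scanner headers; the titles and headers, which give channel 1 as Cy3 and channel 2 as Cy5, were followed, so the sign of each log2 Cy5/Cy3 rests on them. Replicates 1 and 3 are B49.5 and replicates 2 and 4 are J21.c3, as numbered in the titles. The scanner headers place replicates 1 and 2 in hybridisation batch 1 and replicates 3 and 4 in batch 2, show B49.5 replicate 1 imaged on another scanner than the other 3 arrays, and name its cells B49.6 in the image name; the title was followed.

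The spot intensity values deposited are amplitudes fitted by BlueFuse 3.2, per the file headers, for 30000 spots in 48 print blocks. No background column was found. The planned normexp correction applied unless the values were already corrected; whether fitting removed the background is not given in the sources used here, and the amplitudes were used as given, with normexp at offset 50 as an alternative. The headers also place the spots on NCBI build 35. The probability of signal per channel is a fraction from 0 to 1 that BlueFuse computed, per the file headers. The log2 ratios deposited in the series' value table equal the scanner's unnormalized log2 Cy5/Cy3 on 3 arrays and its negative on J21.c3 replicate 2, with column medians of -0.64, -0.03, 0.17 and 0.21 for replicates 1 to 4. A compiled table of log2 ratios, whose making the sources used here do not give, holds 27586 rows, as many as there are spots with a genome position, and 3 of its columns match the scanner's ratios after a loess within print blocks. Its column named for experiment 1 and B49.5 correlates at -0.999 with J21.c3 replicate 2, those for experiments 3 and 4 at -1.000 and 1.000 with B49.5 replicate 3 and J21.c3 replicate 4, and that for experiment 2 matched no array (highest correlation 0.641, with B49.5 replicate 1, over probes with signal on all arrays). Its column medians are 0.01, 0.04, 0.02 and -0.02. Its direction is therefore mixed, and both tables served only as alternatives.

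Work was done in R 4.3.3 with limma 3.58.1. Log ratios were normalized by loess within each array, with the 48 blank and 50 empty spots given no weight and then left out. No spot was marked as excluded. Spots near the top of the scale, taken as 60000 or more in a channel, were kept; there were 102, 78, 306 and 102 of them on replicates 1 to 4, and none of the 20 genes named for abundance had one. Spots of 1 accession were averaged. For abundance, the mean log2 intensity of both channels was quantile normalized between arrays, since the cells never shared an array. Probes with a signal probability above 0.5 in both channels on at least 2 arrays were tested, 13491 of 28831; 64 probes of genes not reported here were left out first, and the value of 1 other gene is not reported here. Of the probes, 13478 were named through their accession in a RefSeq table of assembly GRCh38.p14, used for names only, and 815 through the symbol in their description; 60 whose accession and description disagreed, and all others, stayed unnamed. Different probes of a gene were averaged for gene lists.

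Spot names were checked against the signals. Of 56 single-spot probes of ribosomal proteins, 50 (89.3%) lay in the brightest 10% of spots. The 760 probes with 2 spots did not agree between them: 1 spot lies in row 5 and the other in row 25 of the same block, and their log2 intensities correlated between -0.03 and 0.09 over probes. So at least 1 of each such pair may not carry the named probe; 246 of these probes were tested, and the limits and the counts of calls were repeated without them. The 142 pairs of tested probes that share a UniGene cluster correlated at 0.18 to 0.25 in intensity and at -0.07 in their difference between the cells. Of the repeated GAPDH spots, which lie in 4 blocks, 297 carried signal on all arrays.

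The 99% limits are the 0.5 and 99.5 percentiles of log2 Cy5/Cy3 per array. Tests used limma's lmFit and eBayes with Benjamini-Hochberg adjustment at 0.05: the mean ratio of 4 arrays against 0, and B49.5 minus J21.c3 for ratios and for abundance, without the batch as planned and with it as a block. Gene lists, 32 of them with at least 3 measured members, were tested with camera at a preset correlation of 0.01 on 8527 genes. Genes named are the 10 with the smallest p in each direction of the abundance comparison, as fewer than 10 passed, the 3 in each direction for the dye effect, up to 4 members of a list called by camera, and 6 housekeeping genes; others are said to be chosen after their values were seen. A probe without signal on any array of the dimmer cells has only a bound on its fold. Other background corrections, normalizations, filters, thresholds, channels, models, left-out arrays and the deposited tables were tried as alternatives.

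The steps were tested on simulated data of 13491 probes, with 200 probes changed, 50 at each fold. For abundance these took the real means and the real batch shifts, shuffled over probes. Their spread was drawn as independent normal values from the prior that the fit with the batch as a block gave on the real arrays. For the ratios they held no batch shift and took the arrays as independent. The real ratios of B49.5 replicate 3 and J21.c3 replicate 4 correlated at 0.715, so the ratio recoveries and false calls may not hold for the real arrays. For abundance without the batch, 0% of the probes changed 16-fold were recovered. With the batch as a block, 8% of 2-fold, 96% of 4-fold and 100% of 8-fold changes were recovered, with 8 false calls. For the mean ratio, 22% of 2-fold and 92% of 4-fold changes were recovered, with 6 false calls, and for the ratio difference between cells 0% of 4-fold, 24% of 8-fold and 84% of 16-fold, with 5 false calls. With no change, neither abundance model called a probe. As the spread came from the prior of the fit with the block, these values do not test whether that fit's assumptions hold for the real arrays. The number of arrays limits the precision of every value.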

Results

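Expression was measured on 4 two-colour spotted arrays in human cells known only by the code names B49.5 and J21.c3. Each array was a self-self hybridisation: 1 culture was divided, the RNA of one part was labelled with Cy3 and that of the other part with Cy5, and both were hybridised together. B49.5 was measured on replicates 1 and 3 and J21.c3 on replicates 2 and 4. Replicates 1 and 2 formed hybridisation batch 1 and replicates 3 and 4 batch 2, so each batch held both kinds of cells. Of 28831 probes, 13491 carried signal in both channels on at least 2 arrays and were tested; 8571 of these had a single gene symbol. The share of reported probes with signal in both channels was 37.3% in B49.5 replicate 1, 40.6% in J21.c3 replicate 2, 47.4% in B49.5 replicate 3 and 46.3% in J21.c3 replicate 4. Mean spot amplitude per channel ranged from 1924 to 2749. The labels call the 4 arrays biological replicates and the scanner headers call them technical, so p-values may measure only the spread between hybridisations.

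The first question, given by the series title, was how far log2 Cy5/Cy3 spreads when the same cells are in both channels. The central 99% of probes lay between -2.03 ± 0.30 and 1.52 ± 0.53 (mean ± SD, n = 4 arrays). The housekeeping probes lay inside the limits of their array. On B49.5 replicate 1, J21.c3 replicate 2, B49.5 replicate 3 and J21.c3 replicate 4 in turn, the log2 ratio of ACTB, which encodes beta-actin, was 0.23, -0.15, -0.22 and -0.12. The repeated spots of the GAPDH probe M33197 averaged -0.13, -0.09, -0.06 and -0.13, and RPLP0, a ribosomal stalk protein, gave 0.16, 0.25, 0.34 and 0.30. TUBA1A, a tubulin, gave 0.25, 0.03, 0.41 and 1.03. PPIA, which encodes cyclophilin A, ranged from -1.34 to 0.05 and B2M, beta-2-microglobulin, from -0.65 to 0.77. RPLP0 lay near the top of the amplitude scale, at 60000 or more in a channel, on 4 arrays and ACTB and TUBA1A on 3, as did 192 of the GAPDH spots on B49.5 replicate 3, so these ratios may be compressed. Over the GAPDH spots of an array the SD of log2 Cy5/Cy3 was 0.38 ± 0.05 (SD, n = 4).

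The limits differed between arrays. They were -2.40 and 2.07 in B49.5 replicate 1, -1.92 and 0.89 in J21.c3 replicate 2, -1.68 and 1.29 in B49.5 replicate 3, and -2.10 and 1.82 in J21.c3 replicate 4. As folds, the mean limits were 4.14 ± 0.89 towards Cy3 and 3.01 ± 1.05 towards Cy5 (SD, n = 4). The share of probes beyond 2-fold was 10.6% ± 6.3 (SD, n = 4), from 4.16% in J21.c3 replicate 2 to 19.3% in J21.c3 replicate 4. Beyond 1.5-fold it was 28.7% ± 14.2. In the dimmest 1349 probes of each array the limits were -2.60 ± 0.52 and 2.08 ± 1.06 and 33.9% ± 21.4 of probes lay beyond 2-fold, against -1.24 ± 0.56, 1.08 ± 0.50 and 5.83% ± 8.11 in the brightest 1350 (SD, n = 4), where probes near the top of the scale, 138 of those tested on any array, lie. The width of the interval, 3.54, was 2.56 over probes with signal on all 4 arrays and 5.18 with no filter.

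**Figure D1:**
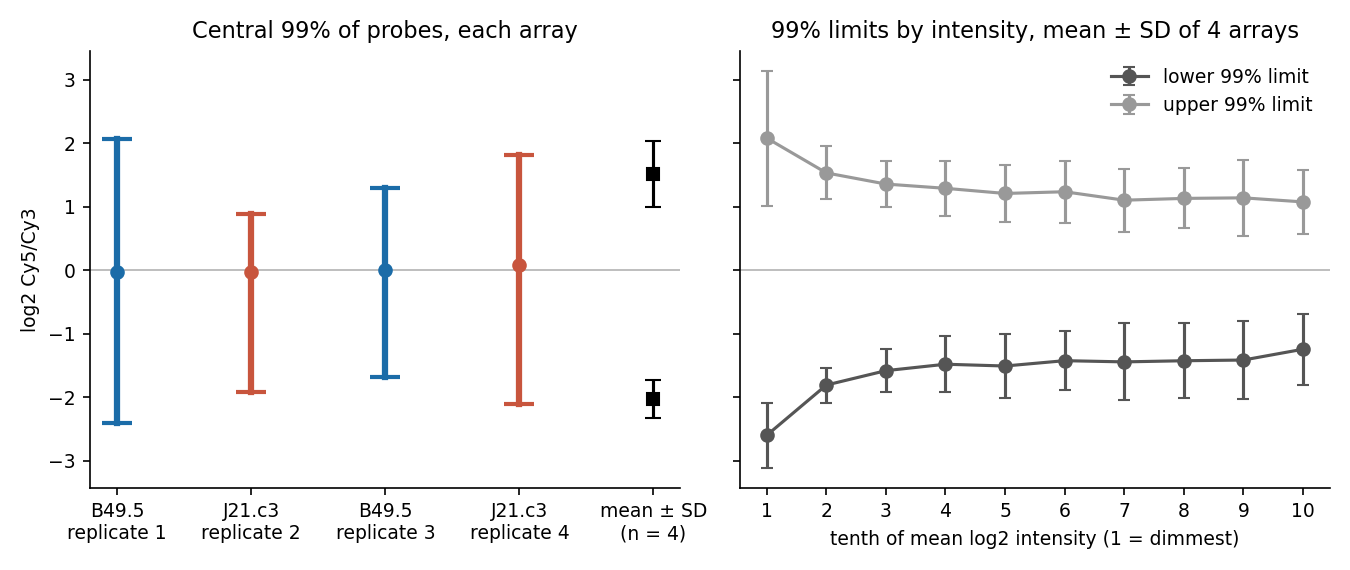
Limits that hold the central 99% of log2 Cy5/Cy3 values. Left, each array, with bars from the lower to the upper limit, a point at the median and the mean limits ± SD over 4 arrays in black; right, mean limits ± SD of 4 arrays over 10 groups of probes by mean log2 intensity, with limits of -2.60 and 2.08 in the dimmest group and -1.24 and 1.08 in the brightest.

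A mean ratio away from 0 over all arrays would be an effect of dye, probe or place on the slide. Both channels held the same cells, and each probe kept its place on every array. The 3 probes with the smallest p towards Cy3 were those of the chemokine receptor gene CXCR3 (mean log2 Cy5/Cy3 -1.51, SE 0.18), the beta-defensin gene DEFB108A (-1.76, SE 0.22) and the RNA-binding protein gene RBM24 (-1.34, SE 0.20). Towards Cy5 they were LZIC (0.93, SE 0.19), the apolipoprotein gene APOA1 (0.94, SE 0.19) and the exocyst gene EXOC4 (0.86, SE 0.18). Each of these 6 had the same sign on 4 of 4 arrays, which their choice by p over these same arrays favours. None of the 6 passed the test (limma adjusted p = 0.352). The APOA1 and EXOC4 values each average a pair of spots whose intensities did not go together over such probes (correlation from -0.03 to 0.09). No probe of 13491 passed with limma, and 1880 had an unadjusted p under 0.05, against 675 expected by chance. That number moved with the arrays used: it was 669 of 11547 without J21.c3 replicate 4, 722 of 11522 without B49.5 replicate 3, 1384 of 12757 without J21.c3 replicate 2 and 3123 of 12998 without B49.5 replicate 1. The 675 expected by chance take the arrays as independent, while the ratios of B49.5 replicate 3 and J21.c3 replicate 4 correlated at 0.715. The excess over that number is therefore no firm sign of a dye effect. With the batch as a block 0 probes passed limma's test and 4082 had an unadjusted p under 0.05. Over the 8962 probes with signal on all arrays, 2 passed, those of CXCR3 and DEFB108A (limma adjusted p = 0.0411).

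Whether the self-self ratio depended on the cells was asked by setting B49.5 against J21.c3. No probe passed with limma, 77 had an unadjusted p under 0.05, and with the hybridisation batch as a block 0 passed and 545 had an unadjusted p under 0.05. Within a single batch 1 array stands against 1, so a batch taken alone gives no test. Leaving out an array changed the count: it was 30 without B49.5 replicate 3, 1 without B49.5 replicate 1 (probe AK090573) and 5 without J21.c3 replicate 4 (ERI2, AZIN2, CSAD and the probes AK091116 and BC011455), names chosen after their values were seen.

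The mean self-self limits were next set beside differences in mean log2 intensity between arrays. The limits come from ratios of single channels, while these differences are of means of both channels after quantile normalization. The shares therefore serve to compare pairs of arrays, not to be read against the share that the limits leave out. As the limits are not symmetric, each share also depends on which array comes first, here that with the lower replicate number. Probes beyond the limits made up 9.36% for the B49.5 arrays and 6.04% for the J21.c3 arrays, each pair being the same cells in different batches. Between B49.5 and J21.c3 hybridised in the same batch the share was 3.86% in batch 1 and 2.41% in batch 2. Between different cells in different batches it was 9.76% and 8.70%. Intensities correlated over probes at 0.883 and 0.912 for different cells in the same batch, and at 0.792 and 0.816 for the same cells in different batches; probes are not independent replicates. No probe passed limma's test between the batches, with a smallest adjusted p of 0.0505. That fit leaves 2 residual degrees of freedom, and 3335 probes had an unadjusted p under 0.05, against 675 expected by chance.

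**Figure D2:**
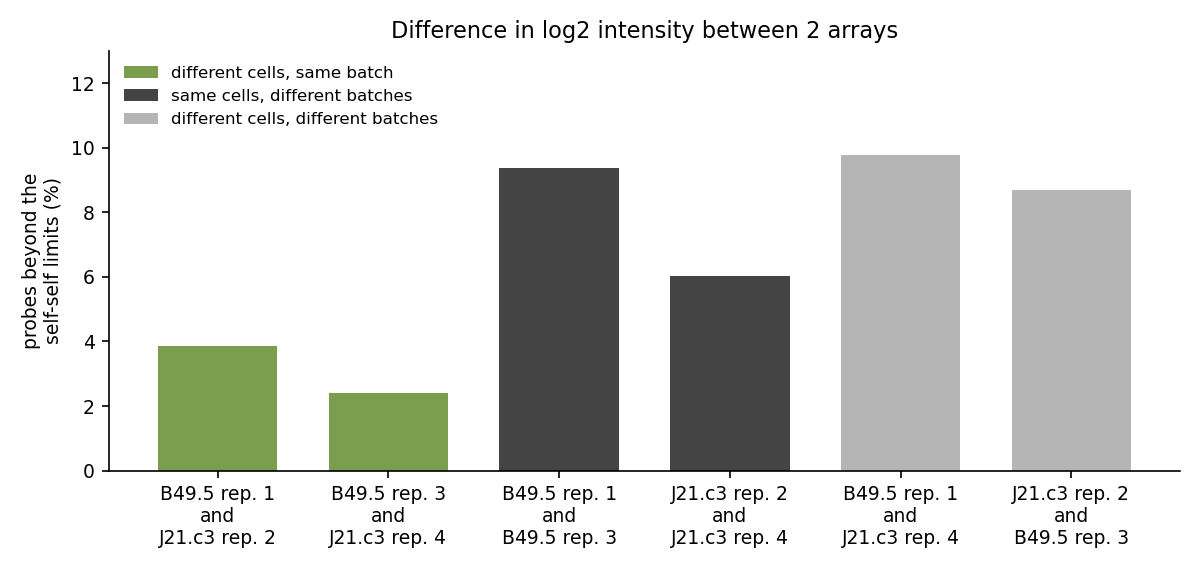
Percent of 13491 probes whose difference in mean log2 intensity between 2 arrays lies beyond the self-self 99% limits, for each of the 6 pairs of arrays (1 bar per pair). Different cells in the same batch gave 3.86% and 2.41%, and the same cells in different batches 9.36% and 6.04%.

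The abundance comparison asked which transcripts differed between B49.5 and J21.c3; the genes named here had the smallest p values, and none passed limma's test without the hybridisation batch as a block. GNB1, which encodes a beta subunit of heterotrimeric G proteins (probe NM_002074, chromosome 1, position 1750302 of NCBI build 35), carried signal on both J21.c3 arrays and on neither B49.5 array, higher in J21.c3 by at least 5.63 on the log2 scale. Within the batches, B49.5 minus J21.c3 was bounded at -5.24 in batch 1 and -6.02 in batch 2 (limma adjusted p = 0.143, and 1.3e-19 with the batch as a block). GAL, which encodes the neuropeptide galanin (NM_015973, chromosome 11, position 68215088), carried signal on both B49.5 arrays only and was at least 6.61-fold higher there. The integrin gene ITGA6 (NM_000210, chromosome 2, position 173194885) was 9.17-fold higher in B49.5, by 4.06 log2 units in batch 1 and 2.33 in batch 2. THBS1, which encodes the matrix glycoprotein thrombospondin 1 (NM_003246, chromosome 15, position 37675043), was at least 11.4-fold higher in J21.c3 and SERPINB2, an inhibitor of plasminogen activators (NM_002575, chromosome 18, position 59713538), at least 9.58-fold. These bounds set the brighter cells' mean against the lowest signal among probes with signal, or the probe's own where higher, while the p values and counts take the intensities of probes without signal as measured.

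With limma no probe passed for abundance without the batch as a block, a test that recovered 0% of probes changed 16-fold in simulated data. At an unadjusted p under 0.05 there were 258 probes, against 675 expected by chance, and 20 genes are named by rank alone. Besides GAL and ITGA6, those higher in B49.5 were LRRC17 (log2 difference 2.92, SE 0.66), MRPL48, a mitochondrial ribosomal protein gene (2.66, SE 0.58), CPED1 (2.53, SE 0.51), LRRK1 (at least 3.88-fold, with signal in B49.5 only), the adhesion molecule gene ICAM2 (2.04, SE 0.49), the lysophosphatidic acid receptor gene LPAR3 (2.00, SE 0.52), the nuclear envelope gene SYNE1 (1.87, SE 0.48) and the flap endonuclease gene FEN1 (1.81, SE 0.48). Besides GNB1, THBS1 and SERPINB2, those higher in J21.c3 were BEX1 (-3.49, SE 0.60), ANKRD36B, the prostaglandin E synthase gene PTGES, the annexin gene ANXA10, FEZ1, DBNDD2 (-2.42, SE 0.52) and the follistatin gene FST (-2.13, SE 0.49). LRRC17, MRPL48, ICAM2, LPAR3 and SYNE1 carried signal on both B49.5 arrays but on only 1 J21.c3 array. BEX1 did so on both J21.c3 arrays but on only 1 B49.5 array. The differences of these genes are thus partly against background. ANKRD36B, PTGES, ANXA10 and FEZ1 carried signal in J21.c3 only, where they were at least 9.94-fold, 5.33-fold, 5.48-fold and 4.41-fold higher. The limma adjusted p of these genes was 1, apart from 0.143 for GNB1. The count of probes past the test was 26 without B49.5 replicate 1 and 66 without B49.5 replicate 3, and 1, GNB1, when the 8 channels entered with the array as a random block.

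All 20 named genes, which were chosen by p from these same arrays, passed with the hybridisation batch as a block. With that block 341 probes passed, 219 higher in B49.5 and 122 higher in J21.c3. That fit leaves 1 residual degree of freedom, so nearly all of its estimate of spread is shared over probes, and the count was 74 after a normexp background correction, 43 of them higher in B49.5. When only the tested probes entered the quantile normalization it was 30 and the balance turned round, with 11 higher in B49.5 and 19 higher in J21.c3. Without a model, 291 probes differed at least 2-fold in the same direction within each batch, 180 higher in B49.5 and 111 higher in J21.c3, against 64 in opposite directions. Shuffling the probes of 1 batch 1000 times gave 112.3 on average and at most 148 in the same direction. At 4-fold the counts were 25 in the same direction and 3 in opposite directions.

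**Figure D3:**
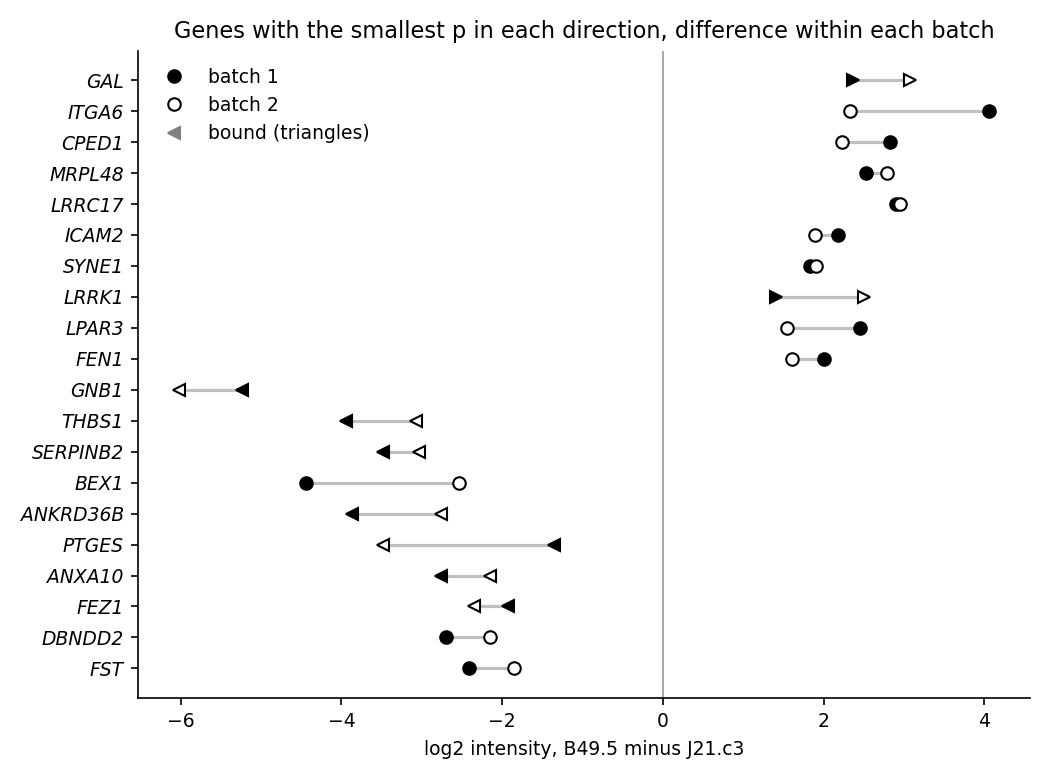
Difference in log2 intensity, B49.5 minus J21.c3, within batch 1 (filled) and batch 2 (open) for the 10 genes with the smallest p in each direction; triangles are bounds for genes without signal in the dimmer cells, such as GNB1 at -5.24 and -6.02. Each value or bound lies on the same side of 0 in both batches, which the choice of genes by p over these same arrays favours. None of the genes passed limma without the batch as a block.

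Of 32 gene lists fixed beforehand, 1 was called by limma's camera, that of cholesterol synthesis, which was higher in B49.5 (median log2 difference 0.44 over 18 measured genes, adjusted p = 0.0326). The call was lost with an estimated correlation (camera adjusted p = 0.942) and with fry (adjusted p = 0.641). Fry tests whether the genes move one way on balance. The estimated correlation was -0.0456, below the preset 0.01, so correlation between members does not account for the first loss. With an estimated correlation camera rests on the fit's 2 residual degrees of freedom, and 0 of the lists were called. Of its 18 genes, 13 had a higher mean in B49.5, 12 of them in both batches. Without the batch as a block no member passed the test over all genes or when adjusted over the list alone, and with it FDFT1 and CYP51A1 passed over all genes and 3 members when adjusted over the list alone. The members with the smallest p were FDFT1, the squalene synthase gene (1.64, SE 0.51), CYP51A1, the lanosterol demethylase gene (1.72, SE 0.58), MSMO1, a sterol oxidase gene (1.41, SE 0.53), and SQLE, the squalene epoxidase gene (1.05, SE 0.50). In both batches 3 members were lower in B49.5, among them SREBF1, a regulator of lipid synthesis chosen after its value was seen (-0.78, SE 0.47). The list's median was 0.40 in batch 1 and 0.51 in batch 2, and camera gave an adjusted p of 0.0365 with the batch as a block. The call was also lost without B49.5 replicate 1 (adjusted p = 0.192), B49.5 replicate 3 (adjusted p = 0.44) or J21.c3 replicate 4 (adjusted p = 0.571).

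Among the other lists, matrix proteases and their inhibitors were lower in B49.5 with the batch as a block (camera adjusted p = 0.0365) and not past the threshold without it (adjusted p = 0.165, and 0.942 with an estimated correlation). They were also the list called without B49.5 replicate 1. Their median was -0.14 over 26 genes, -0.05 in batch 1 and -0.26 in batch 2. When adjusted over the list alone, 1 member, SERPINB2, passed without the block and 4 members with it. Without the block THBS1 also passed within the list of TGF-beta targets and ITGA6 within that of integrins and adhesion, and no gene of any list passed over all genes; with it 187 of 8527 genes did. The ribosomal proteins had a median of 0.02 over 54 genes (camera adjusted p = 0.725), but 45 of their 54 probes lay near the top of the scale on at least 1 array, where differences may be compressed. The cell cycle list was at -0.20 over 38 (adjusted p = 0.528) and the oxidative phosphorylation list at 0.10 over 50 (adjusted p = 0.203), the latter called with median scaling and without J21.c3 replicate 2. With an estimated correlation, in the setting reported, its adjusted p was 0.942. No housekeeping probe passed limma's test between the cells (adjusted p = 1). B2M (-0.19, SE 0.50) carried signal on 1 B49.5 array and both J21.c3 arrays and PPIA (0.65, SE 0.78) on 1 array of each, so these differences are partly against background. ACTB (-0.23, SE 0.47), TUBA1A (0.35, SE 0.54) and the GAPDH probe NM_002046 (0.00, SE 0.51) lay near the top of the scale on 3 arrays each, and RPLP0 on all 4, so their differences say little.

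**Figure D4:**
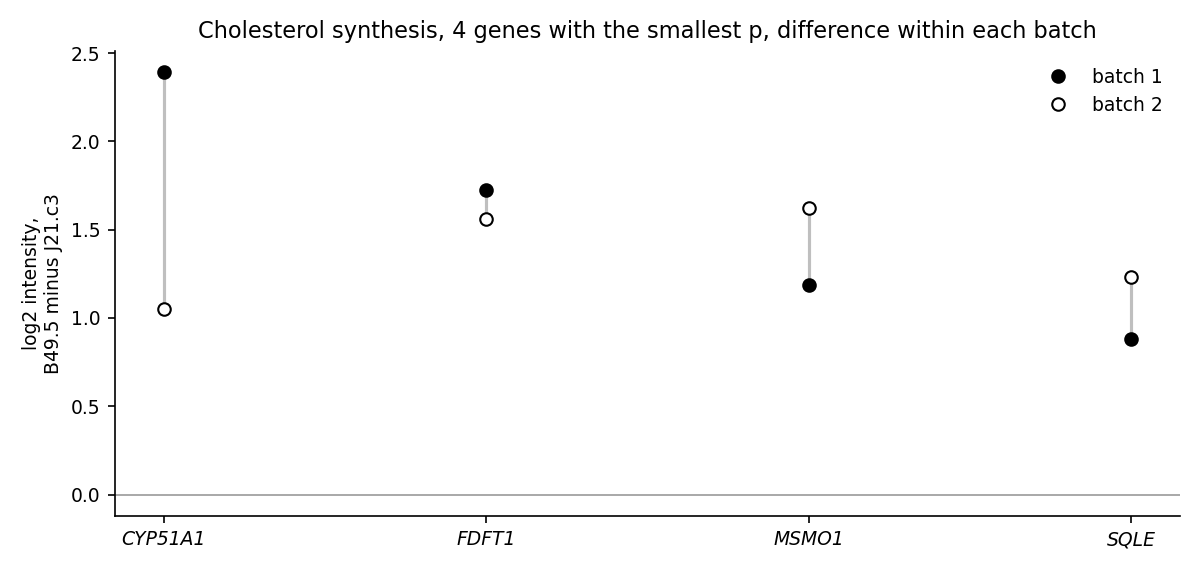
Difference in log2 intensity, B49.5 minus J21.c3, of the 4 cholesterol synthesis genes with the smallest p among 18 measured, within batch 1 (filled) and batch 2 (open). All 4 lie above 0 in both batches, as do 12 of the 18, while 3 of the 18 lie below 0 in both.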

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

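The tests of the shared ratios, of the scanner and of spots near the top of the scale were chosen only after the results they concern were seen. Spots listed as empty carried signal in both channels more often than spots listed as blank, none of whose 48 spots did on any array. Of 50 empty spots, 20% carried signal on B49.5 replicate 1, 18% on J21.c3 replicate 2, 22% on B49.5 replicate 3 and 18% on J21.c3 replicate 4. No array stood apart by Dixon's test on any of 10 measures of limits, spread, signal and GAPDH level.

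The arrays of batch 2, B49.5 replicate 3 and J21.c3 replicate 4, shared their self-self ratios, with a correlation over probes of 0.715, against -0.123 to 0.242 for the other pairs. Dim spots do not account for it, since the correlation was 0.762 over the 4497 brightest probes. Place on the slide remains a candidate explanation for part of it. The repeated spots of the GAPDH probe correlated at 0.361 (0.226, SE 0.0874, over the 119 below the top of the scale on both arrays). Loess within print blocks lowered the correlation over probes to 0.411. The GAPDH spots lie in 4 of 48 blocks. Their log2 intensity varied with an SD of 1.908 on B49.5 replicate 3 and 1.928 on J21.c3 replicate 4, so they did not differ only in place. For probe sequence, the correlation between different spots of a probe was -0.016 (same spot 0.251), but that test is void because the spots of a probe did not go together in intensity. No biological explanation was tested, since both channels held the same cells.

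Array intensities grouped by hybridisation batch and not by cells. The scanner is argued against by J21.c3 replicate 2, which correlated with the array from the other scanner by 0.0666 more than with any array from its own scanner. Dim spots are argued against because, over probes with signal on all arrays, same-batch pairs still correlated by 0.0777 more than same-cell pairs. What differed between the batches beyond scanner and signal is open. No biological explanation was tested, because both batches held both kinds of cells.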

How the results depend on the processing

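Normexp at offset 50 was the background correction planned unless the values were already corrected, and was made an alternative after the data were seen. The settings with the blank level, spots of BlueFuse's confidence class E, probes with 2 spots and turned signs of deposited tables were chosen only after the data were seen. So was the batch block beyond its plain use for abundance. The other settings were chosen before the data were examined. The interval width, 3.54, stayed within the SD between arrays in 14 of 19 alternatives and was 5.95 with the blank level subtracted, 5.18 with no filter, 2.56 for probes on in all arrays, 2.68 in the compiled table and 2.71 to 3.73 with an array left out, lowest without J21.c3 replicate 4. The width does not depend on the sign of a ratio, so its 19 alternatives include the deposited tables. For the counts of calls below, deposited tables with mixed signs test nothing and are left out. So is the compiled table for ratio differences, whose columns for experiments 1 and 2 do not match the arrays they name. A minimum fold added to a count of 0 also tests nothing and is left out. The count of dye effects was 0 in 17 of 19 alternatives, and 2 for probes on in all arrays and in the compiled table with signs turned, there CXCR3 and ADAM11, the latter named after its value was seen, though 1 column of that table matches no array. The count of ratio differences was 0 in 13 of 16 alternatives and 0 to 30 with an array left out. The abundance count was 0 in 16 of 26 alternatives, all 16 of them without the batch as a block. In the reported setting the test without the block recovered 0% of simulated 16-fold changes, so these counts of 0 say little. It was 1 (GNB1) with 8 channels and the array as a random block, and 0 to 66 with an array left out: 26 without B49.5 replicate 1, 66 without B49.5 replicate 3 and 0 without either J21.c3 array. In these fits the lone array is assumed to vary like the others. With the batch as a block the count was 341, and together with it 352 with median scaling, 351 without probes with 2 spots, 265 with an intensity trend and robust prior, 151 for probes on in all arrays, 74 with normexp at offset 50 and 30 with quantile normalization of the tested probes alone; beyond fewer probes tested, the cause was not tested. The median difference of all probes moved from -0.05 to 0.07 with median scaling.

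The mean share of probes beyond the limits, 7.70% for the same cells and 6.18% for different cells, was 12.6% for the same cells with median scaling, 10.4% with normal limits, and 1.70% and 1.38% with no filter. The count of lists called, 1, was 0 with an estimated correlation, with fry and with no filter, 2 with median scaling and with the batch as a block, and 0 to 2 with an array left out, the 1 without B49.5 replicate 1 being matrix proteases and inhibitors. Cholesterol synthesis passed in 6 of 12 settings (median 0.36 to 0.65, adjusted p from 0.00842 to 0.942). Among the 6, taking the brightest probe per gene left the list's median (0.44) and camera adjusted p (0.0326) unchanged, so it adds nothing. The list did not pass without B49.5 replicate 1 (median 0.65), B49.5 replicate 3 (0.53) or J21.c3 replicate 4 (0.36). Local background could not be subtracted, as no background column was given; no spot was marked, so keeping marked spots equals the reported setting, as does no background correction; normalization within arrays leaves abundance as it is; and the compiled table holds no intensities. No pairing by replicate number was possible because B49.5 and J21.c3 share none; the fit with the batch as a block pairs the arrays by batch. Signal over background, 5.2 to 9.07 in Cy3 and 3.03 to 5.99 in Cy5 per the file headers, limits dim probes.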

Other observations

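The tests of exchanged labels, of neighbouring spots and of spots near the top of the scale, and the genes named here beyond the rule, were chosen only after their values were seen. Some lists that camera did not call without the batch as a block held members whose difference had the same sign in both batches and passed with the batch as a block. Among inflammatory NF-kB targets, with a median of -0.11 over 17 genes (camera adjusted p = 0.203), these were the cytokine gene IL1A and RELB, which encodes an NF-kB subunit. Both carried signal in J21.c3 only, where they were at least 3.19-fold and 3.32-fold higher; that fit takes their B49.5 intensities, which are without signal, as measured. In the protease list MMP1, an interstitial collagenase gene, was at -2.73 (SE 0.41 and adjusted p = 2.38e-05 with the block) beside SERPINB2. GDF15, among p53 targets, was at -1.52 (SE 0.40 and adjusted p = 0.0308 with the block). The interferon-induced gene OAS1 went the other way, with signal in B49.5 only and at least 3.28-fold higher there, as did TOP2A, a topoisomerase gene of the cell cycle list (1.51, SE 0.41 and adjusted p = 0.0319 with the block). None of these 6 genes passed without the block. They are not all such members of uncalled lists. With the block, 2 members of the oxidative phosphorylation list and 1 ribosomal protein passed higher in B49.5. So did 2 of the integrins and adhesion list, with 1 lower in B49.5. Of the TGF-beta targets 1 passed lower in B49.5.

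No list of cell type markers was called. The epithelial list had a median of -0.06 over 12 genes and the mesenchymal and fibroblast list 0.18 over 18, with camera adjusted p of 0.725 and 0.917. Adjusted p was 0.752 for the endothelial list, 0.946 for blood, 0.917 for neural, 0.978 for melanocyte, 0.886 for liver and 0.594 for muscle markers. Levels of different probes cannot be set against each other, so no origin was assigned to either.

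The B49.5 minus J21.c3 differences of the batches went together over probes, at a correlation of 0.204. Labels exchanged in 1 batch are argued against as its source, since the cells' differences would then lie in opposite directions: at 2-fold 64 probes did, against 112.1 for shuffled probes and 291 in the same direction (at 4-fold 3, 2.09 and 25). These counts rest on the same agreement as the correlation and do not show that it comes from the cells, and an exchange in both batches was not tested. For place on the slide, the differences of the GAPDH spots correlated at -0.288 between batches (-0.182, SE 0.091, over the 114 below the top of the scale). This gives place no backing there, but these spots vary in intensity and lie in 4 of 48 blocks. They cannot speak for the other blocks. Place shared by neighbouring spots is argued against by the correlation of 0.252 after the mean of each spot's neighbours was taken off (0.209 before). That transcript abundance differs between the cells is a hypothesis that stays open: across the spots of a probe the correlation was 0.00269 (same spot 0.142), and that test is void because those spots did not go together in intensity. Over 142 pairs of different probes of a UniGene cluster the differences correlated at -0.07 (SE 0.08), which gives it no backing, but the intensities of these pairs correlated at 0.18 to 0.25 only. Whether the arrays of each kind of cells came from separate RNA preparations is also open, since labels and headers disagree.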
